A study of Homo sapiens with 113 samples.

How the data were processed

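RNA sequencing of the colon cancer line HCT116 compared ways of making cDNA from single cells. Per the labels, single cells were amplified in tubes with SMARTer (3 libraries), TransPlex (3) or Ovation (7), or with SMARTer chemistry on a microfluidic device (96), and bulk RNA was made into libraries with SuperScript and no amplification (2) or with SMARTer (2). The labels place 4 Ovation libraries with the Nextera kit and 3 with the NEB kit, while the series text counts them as 3 and 4, and the labels were followed. Cells were lysed in tubes or in the device, per the labels' protocols. Of the 96 microfluidic libraries 3 carry the name of a control in their file name, which disagrees with their titles: they were left out of the main results, leaving 93, and put back in an alternative. The 93 came from 4 library pools of up to 24 cells. A further table holds quantitative PCR of single cells.

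Per the submitters' processing notes the reads were handled with cutadapt 1.2.1, Bowtie 0.12.9, Bowtie2 2.1.0, TopHat2 2.0.8 and Cufflinks 2.0.2 on the hg19 genome; the part played by each aligner is not given in the sources used here. The deposited value of each gene is FPKM, fragments scaled to transcript length in kilobases and to library size, with the bounds of its interval. PCR values are the deposited threshold cycles (Ct), where a code of 999 means no product and was taken as undetected.

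FPKM were used as deposited, without scaling between libraries, as log2 of FPKM + 1. Symbols found in all tables were kept (23224), with the rows of a symbol summed for the 536 symbols on several rows, 99 symbols missing from some table left out, and 92 ERCC spike-ins held apart. Rows whose status reported a failed estimate were taken as missing. Transcript length and GC content were matched by symbol alone to GENCODE 29, which is on another genome build, and no coordinates were taken from it; gene positions in the text are those of the deposited tables on hg19, converted to 1-based. Of 11302 genes at a mean FPKM of 1 or more in bulk SuperScript (bulk-expressed), 97.1% found an annotation and 84 were shorter than 300 nt. Names of 2 joined genes (109) were kept out of rankings.

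Library depth was not in the tables, so fragments were estimated from each interval, taken to span 2 SD either way of a count. The estimate gave 15458304 in bulk SuperScript, 18038740 in bulk SMARTer, 2628649 to 18671304 in tube SMARTer, 1530407 to 3485294 in TransPlex, 3595731 to 12490036 in Ovation-Nextera, 2755460 to 4379600 in Ovation-NEB and a median of 586571 in microfluidic cells (10565.4 to 1899106). For a transcript of 1 kb, FPKM 1 therefore stands for 15.5 fragments in bulk SuperScript and 0.587 in the median microfluidic cell, so low values of single cells rest on very few fragments. At equal depth, libraries were thinned to 100000 implied fragments of genes, with spike-ins not counted, which 85 of 93 microfluidic cells reached.

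Detection was FPKM 1 or more. Agreement was Pearson r across bulk-expressed genes between a library and the mean of bulk SuperScript, between libraries of a method, and between the mean FPKM of a method's cells and bulk, with 100 draws of 3 microfluidic cells for equal numbers. The 20 gene lists were written before the data were examined, as were the groups, comparisons and first set of alternatives. Each list's median log2 difference was placed among 10000 random lists matched in 20 bins of level. Genes were named by rule: at FPKM 10 or more in either group and, in bulk, adjusted p below 0.05 with the 12 highest and 12 lowest fold changes, or, in cells, no overlap between the groups (the 5th to 95th percentile of the microfluidic cells) with the 10 highest and 10 lowest differences, plus 4 members of each list. Because small RNAs filled the rankings, rankings of genes of 300 nt or more were added, chosen after their values were seen, as were the rankings of variable genes in at least 50% of cells and the genes INS, SNAP25, STMN2 and GPM6A.

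The bulk kits were compared with limma 3.58.1 (linear model with a variance trend) in R 4.3.3 over genes at a mean FPKM of 1 or more, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with the correlation estimated. With 2 libraries per kit the estimated setting has few degrees of freedom and can hardly call a list. Lists were also tested with fry, which tests the direction of a list and not its rank among others. Single-cell groups were described without tests, as each method is 1 sample. Cell to cell variability was the squared coefficient of variation against a lowess trend (fraction 0.3) on mean FPKM for genes at 10 or more, and covariation the mean Spearman rho over pairs of list members across cells, against 1000 random lists drawn from 9082 genes. PCR levels were 40 minus the median Ct, with undetected reactions at 40 cycles. Of 641 reaction rows, controls and 6 rows with more than 1 cell were left out. Repeat runs of a chip were averaged per cell where both gave a product. The levels were compared by Spearman rho with the median over microfluidic cells of log2 of FPKM + 1.

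Simulated data with known changes were used to test the scripts: the bulk model recovered 100% of 100 genes changed by log2 1 or 2 with 12 false calls among 11286 genes, the variability measure found 87 of 100 noisy genes, and a planted covarying list reached percentile 100 while an unplanted one reached 68. Alternatives varied the pseudocount, the gene filter, the FPKM or TPM scale, the detection limit, the reference, the correlation, the libraries used, and left out each replicate in turn; the closing section gives their effect. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.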

Results

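The deposit held 113 HCT116 libraries, of which 110 entered the results: 2 of bulk RNA made with SuperScript, 2 of bulk RNA made with SMARTer, and 106 labelled as single cells. The single cells came from tube SMARTer (3), TransPlex (3), Ovation with Nextera (4), Ovation with NEB (3) and the microfluidic SMARTer system (93). Single-cell genes were followed through named groups: ribosomal proteins, oxidative phosphorylation, histones, glycolysis, cell cycle, Wnt, p53, immediate early and cholesterol genes. The series text calls the cells biological replicates, but the labels name no separate cultures, so each method was 1 sample and its cells describe spread without a test. Values are FPKM as deposited, and a gene was counted as detected at FPKM 1 or more.

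Most messages of the ribosome and the respiratory chain were higher with SMARTer than with SuperScript in bulk RNA (n = 2 and 2). Of 78 ribosomal protein genes, 67 were higher with SMARTer, 4 lower and 7 not different, with a median log2 fold change of 1.33 against -0.30 for all tested genes (adjusted p = 1.18e-13 at a preset correlation of 0.01 between genes, 0.421 with the correlation estimated from the data). RPS19, a small-subunit protein, rose from 83.3 to 1004 FPKM (log2 3.58), RPS27 from 59.6 to 577 (3.25), RPS29 from 246.7 to 2245 (3.18) and RPS14 from 383.6 to 2982 (2.95). Nuclear genes of oxidative phosphorylation were higher in 52 of 60 cases and lower in 5 (median 1.54, adjusted p = 1.14e-11 at the preset and 0.421 at the estimated correlation), led by ATP5I (2.82), COX6A1 (2.78) and NDUFA13 (2.77). CYC1, the cytochrome c1 subunit of complex III, went the other way, from 71.1 to 6.10 FPKM (-3.34). HIST1H4C, a histone H4 gene at position 26104176 to 26104565 of chromosome 6, rose from 3.52 to 2369.9 FPKM (9.13), and 8 of 9 tested histone genes were higher (median 1.02, adjusted p = 0.00514 at the preset and 0.421 at the estimated correlation), HIST1H1E, HIST1H1C (3.14) and HIST1H2BK (1.02) among them. Histone genes have near-identical copies among which the authors' counting could split reads, so single histone values are uncertain.

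Most very long transcripts were lower with SMARTer in bulk RNA. Among 42 such genes, 38 were lower and 1 higher (median -1.23, adjusted p = 8.73e-05 at the preset and 0.688 at the estimated correlation), with filamin A, FLNA, at -3.44, the sorting protein gene VPS13A at -3.10 and the scaffold gene AHNAK at -3.03 (61.1 to 6.62 FPKM). NEAT1, the nuclear long noncoding RNA of paraspeckles at position 65190269 to 65194003 of chromosome 11, fell from 121.5 to 2.39 FPKM (-5.17). Genes of 300 nt or more with the lowest values also included the dynein light chain DYNLL2 (88.0 to 0.952 FPKM, -5.51), the RNA-binding protein MSI2 (-4.69), the protease CTSZ (-4.52), the corepressor TRIM28 (-4.52), the splicing factor SRRM2 (-4.34), PTMS (43.4 to 1.32 FPKM), PSMD3 (-4.19) and SNRNP70 (19.9 to 0.186 FPKM). At the upper end stood the RNA-binding gene SLIRP (49.6 to 543 FPKM, 3.43), the protease inhibitor SLPI (7.46 to 76.2 FPKM), the 45S ribosomal RNA precursor RN45S (139 to 1215 FPKM) and the stress gene DDIT3 (18.7 to 167 FPKM). The largest ratios belonged to small RNAs, which are shorter than a typical fragment and often lie inside host genes, so their FPKM is uncertain. SCARNA22 was listed at 0 with SuperScript and at 847.5 FPKM with SMARTer, SNORD76 at 3873 and 0, SNORA61 at 190.3 and 0, and the near-identical SNAR copies SNAR-B2 and SNAR-A1 at 0 and 207 or 182 FPKM.

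Further gene groups held genes that went either way in bulk RNA. Housekeeping genes were higher in 14 of 20 cases (median 0.57, and -0.29 on the TPM scale, adjusted p = 0.00596 at the preset and 0.688 at the estimated correlation), with B2M at 572.5 and 2177 FPKM (1.92) and the actin gene ACTB at 265 and 962 (1.86), while the polymerase gene POLR2A fell (-2.78). G2/M genes were higher in 31 of 51 cases and lower in 15 (median 0.38, and -0.44 on the TPM scale, adjusted p = 0.0133 at the preset and 0.688 at the estimated correlation), CKS1B (50.0 to 259 FPKM) and the securin gene PTTG1 (2.19) in 1 direction, CDC25B (-2.60) and the centromere gene CENPA (-2.26) in the other. Immediate early and stress genes had 20 lower and 7 higher of 30 (median -1.44, adjusted p = 0.0826), with the transcription factor genes FOS (104 to 4.55 FPKM, -4.25) and FOSB (-3.61), IER2 (-3.33) and the phosphatase gene DUSP1 (-3.19). Small nuclear and nucleolar RNAs had 7 higher and 2 lower of 16 (median 1.41, adjusted p = 0.0826, but -1.29 over the 9 bulk-expressed members and -2.10 on the TPM scale), with RMRP listed at 0 and at 19.4 FPKM. Glycolysis split into 8 and 8 of 19 (median 0.10, adjusted p = 0.465), TPI1 at 2.38 and the lactate carrier SLC16A3 at -3.44. G1/S genes split into 18 higher and 15 lower of 38 (median 0.18, adjusted p = 0.433), with cyclin E1, CCNE1, at -2.97, TYMS at -2.66 and the histone mRNA-binding gene SLBP at -2.56.

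Lineage and signalling groups were not called by camera in bulk RNA, while fry, a test of direction alone, called Wnt targets, p53 targets and fibroblast genes (adjusted p = 0.0150) and cholesterol synthesis (0.0166). The p-values that follow are those of camera. Wnt targets had 2 higher and 6 lower of 12 (median -0.61, adjusted p = 0.547), with cyclin D1, CCND1, falling from 80.7 to 7.03 FPKM (-3.35) and SOX4 rising (2.61). Of 23 p53 targets 5 were higher and 12 lower (median -0.41, adjusted p = 0.433), GDF15 at -1.94. Colon epithelial genes had 4 higher and 5 lower of 10 (median -0.56, adjusted p = 0.905), the keratin KRT19 (-1.84) and the adhesion gene EPCAM (-1.77) lower and the claudin CLDN7 (1.58) higher. Cholesterol synthesis had 10 and 10 of 21 (median -0.28, adjusted p = 0.688), the regulators SREBF2 (-3.42) and INSIG1 (-2.98) lower and MSMO1 (1.31) higher. Long noncoding RNAs and hosts of small nucleolar RNAs had 6 higher and 5 lower of 14 (median 0.00, adjusted p = 0.466), SNHG5 at 2.63, SNHG7 at -2.37 and TUG1 at -1.93. Fibroblast genes had 1 higher and 4 lower of 7 (median -1.04, adjusted p = 0.433), S100A4 at 1.98. Leukocyte, endothelial and erythroid lists had fewer than 3 tested members, and none of the mitochondrially encoded genes was in the tables.

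Over all genes, 3759 were higher and 5286 lower with SMARTer among 10811 tested, and adjusting over each list alone gave the same counts as adjusting over all genes. The balance depended on the scale: 41.6% of the different genes were higher in FPKM, 12.0% on a TPM scale (1150 higher, 8401 lower), 19.6% on that scale over genes of 300 nt or more, 34.1% with no filter, and 63.9% among genes of FPKM 10 or more, while the TPM scale moved the median of all genes to -1.25. On the TPM scale bulk-expressed ribosomal and respiratory genes kept their direction (0.46 and 0.71), and the housekeeping, G2/M, G1/S and glycolysis medians changed sign. The 2 replicates of each kit were technical replicates of bulk RNA, so the p-values measure technical spread only. All 6 list calls were made at the preset correlation: with the correlation estimated, camera called 0 of 16 lists, with 0 at unadjusted p below 0.05, while fry, a test of direction alone, called 13. The estimated setting has few degrees of freedom with 2 libraries per kit, so it cannot show whether correlation between genes undoes the calls. Histone genes, at an estimated correlation of -0.066, below the preset 0.01, still went from camera adjusted p = 0.00514 to 0.421. The other called lists had estimated correlations above the preset: very long transcripts 0.620, housekeeping 0.217, respiratory 0.0989, ribosomal 0.0859 and G2/M genes 0.0596. Their p-values at the preset may therefore be too small, most of all for very long transcripts. The p-values given for the other lists are those at the preset correlation.

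Detection fell with bulk level in all 5 single-cell methods. The shares given are means at unequal depth, and libraries of the microfluidic system, tube SMARTer and TransPlex overlapped at every level. At bulk FPKM 100 or more these 3 methods ran from 37.9% to 97.6%, 86.7% to 97.1% and 90.3% to 95.4%. Of the 414 genes at bulk FPKM 100 or more, the mean share detected per cell was 95.2% in the microfluidic system, 93.1% in tube SMARTer, 92.7% in TransPlex, 73.2% in Ovation-Nextera and 64.5% in Ovation-NEB. Of 4848 genes at bulk FPKM 10 to 100 the shares were 75.4%, 56.6%, 59.0%, 32.5% and 25.4%, and of 6040 genes at 1 to 10 they were 31.0%, 20.0%, 27.6%, 11.3% and 7.86%. Bulk SMARTer detected 97.9%, 97.9% and 62.3% of the same classes. GAPDH and ACTB, both of general use as reference genes, were detected in 100% of the 93 microfluidic cells. BMI1, a chromatin regulator at 8.39 FPKM in bulk SuperScript and 2.75 in bulk SMARTer, was detected in 10.8% of them. TERT, the telomerase gene at 0.192 and 0.0108 FPKM, was detected in 1.08%.

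Cells of the microfluidic system had 6111 ± 1023 detected genes (SD, range 479 to 7355), TransPlex cells 5393 ± 780.3, tube SMARTer cells 4698 ± 1144, Ovation-Nextera 2698 ± 333 and Ovation-NEB 2069 ± 207, against 11286.5 in bulk SuperScript and 9189.5 in bulk SMARTer. These counts came at unequal depth: the implied number of fragments had a median of 586571 in the microfluidic cells and ranged from 2628649 to 18671304 in tube SMARTer. The microfluidic lead over TransPlex held at FPKM 1 and at FPKM 10 (3359 and 1149.7 genes) but turned round for any value above 0 (7415 and 10217), on the TPM scale (TransPlex 7216) and at equal implied fragments (5981 and 7123). For any value above 0 tube SMARTer (8711) also passed the microfluidic cells (7415). Ovation-NEB had the fewest genes under every choice. Between the 4 library pools of the microfluidic cells the means ran from 5686 to 6463 genes.

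**Figure D1:**
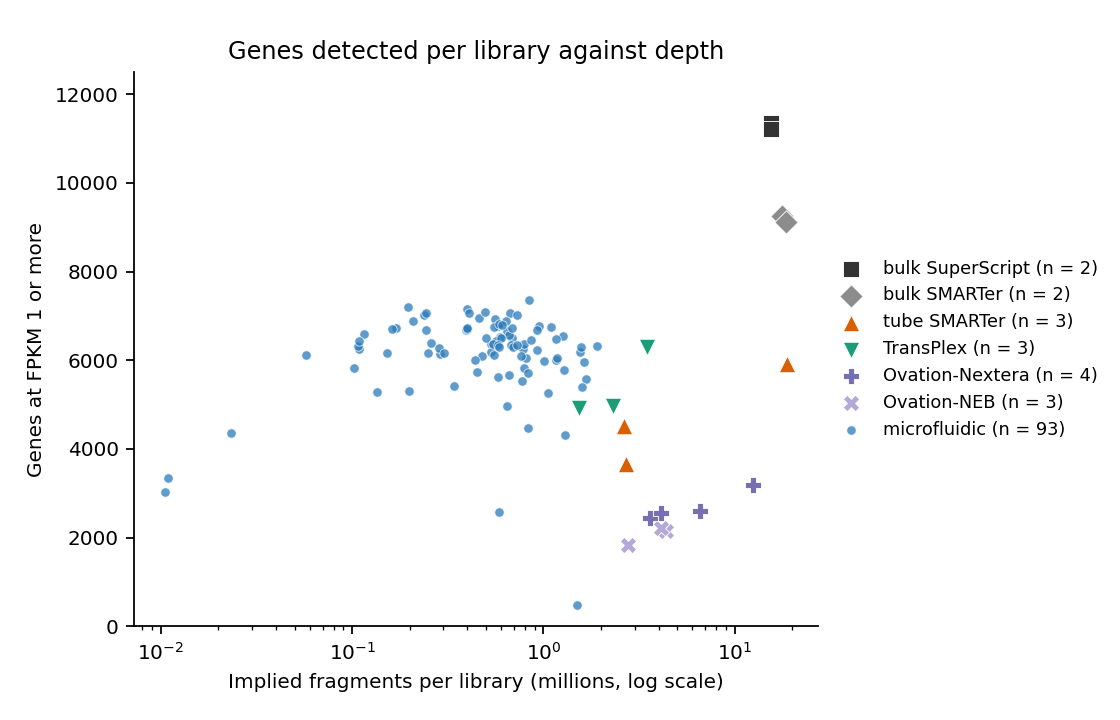
Genes detected at FPKM 1 or more in each library against the number of fragments implied by the authors' confidence intervals (log scale). Colours mark the 7 groups, and each dot is a library.

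Profiles of single cells followed bulk SuperScript across the 11302 bulk-expressed genes most closely in the microfluidic system, with r = 0.689 ± 0.0547 (SD over 93 cells). Tube SMARTer had 0.597 ± 0.0777, TransPlex 0.550 ± 0.0309, Ovation-Nextera 0.418 ± 0.0581, Ovation-NEB 0.383 ± 0.0663 and bulk SMARTer 0.818. These correlations run across genes, which are not independent replicates. Between libraries of a method the median r was 0.700 in the microfluidic system, 0.634 in TransPlex, 0.581 in tube SMARTer, 0.533 in Ovation-Nextera and 0.434 in Ovation-NEB, against 0.969 and 0.986 for the bulk pairs. Averaging cells raised the value: the mean of all 93 microfluidic cells had r = 0.849 with bulk SuperScript, draws of 3 cells 0.774 ± 0.0111, 10 cells 0.819 and 30 cells 0.839. With 3 libraries tube SMARTer reached 0.698, TransPlex 0.626 and Ovation-NEB 0.470, and 4 Ovation-Nextera libraries 0.502. Ovation-Nextera 2 and 4 correlated at 0.995, so the Ovation-Nextera libraries may not be separate cells. Bulk SMARTer as the reference gave 0.739 for the microfluidic cells, 0.592 for tube SMARTer, 0.491 for TransPlex, 0.354 for Ovation-Nextera and 0.323 for Ovation-NEB.

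Ribosomal protein genes were retained above other genes of their bulk level in all 5 single-cell methods. Their median log2 difference was 0.46 in tube SMARTer and 0.45 in the microfluidic cells, where all bulk-expressed genes had -1.90 and -1.39, and both lay at percentile 100 of 10000 random lists matched for bulk level. Respiratory chain genes had 0.23 and 1.12 (both percentile 100), although the TPM scale turned the tube SMARTer value to -0.30. With bulk SMARTer as the reference the ribosomal values turned to -0.93 and -0.88 and the respiratory ones to -1.26 and -0.37. In TransPlex the same 2 groups had, against bulk SuperScript, -1.25 and -1.51 against -2.20 for all genes (percentile 100), with the sign changing to 0.62 and 0.01 on a TPM scale over genes of 300 nt or more. In Ovation-Nextera they had -3.19 (percentile 99.9) and -3.83 (39.8) against -2.54 for all genes, and in Ovation-NEB -3.82 (99.2) and -4.00 (58.8) against -2.70. On the TPM scale the all-gene values were -3.04, -3.06, -3.57, -3.79 and -2.38 in the order tube SMARTer, TransPlex, Ovation-Nextera, Ovation-NEB, microfluidic. Histone genes stood out in TransPlex (2.18 for 6 bulk-expressed members, percentile 100) and lay at -0.97 in tube SMARTer, -0.38 in the microfluidic cells, -1.87 in Ovation-Nextera and -1.80 in Ovation-NEB.

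**Figure D2:**
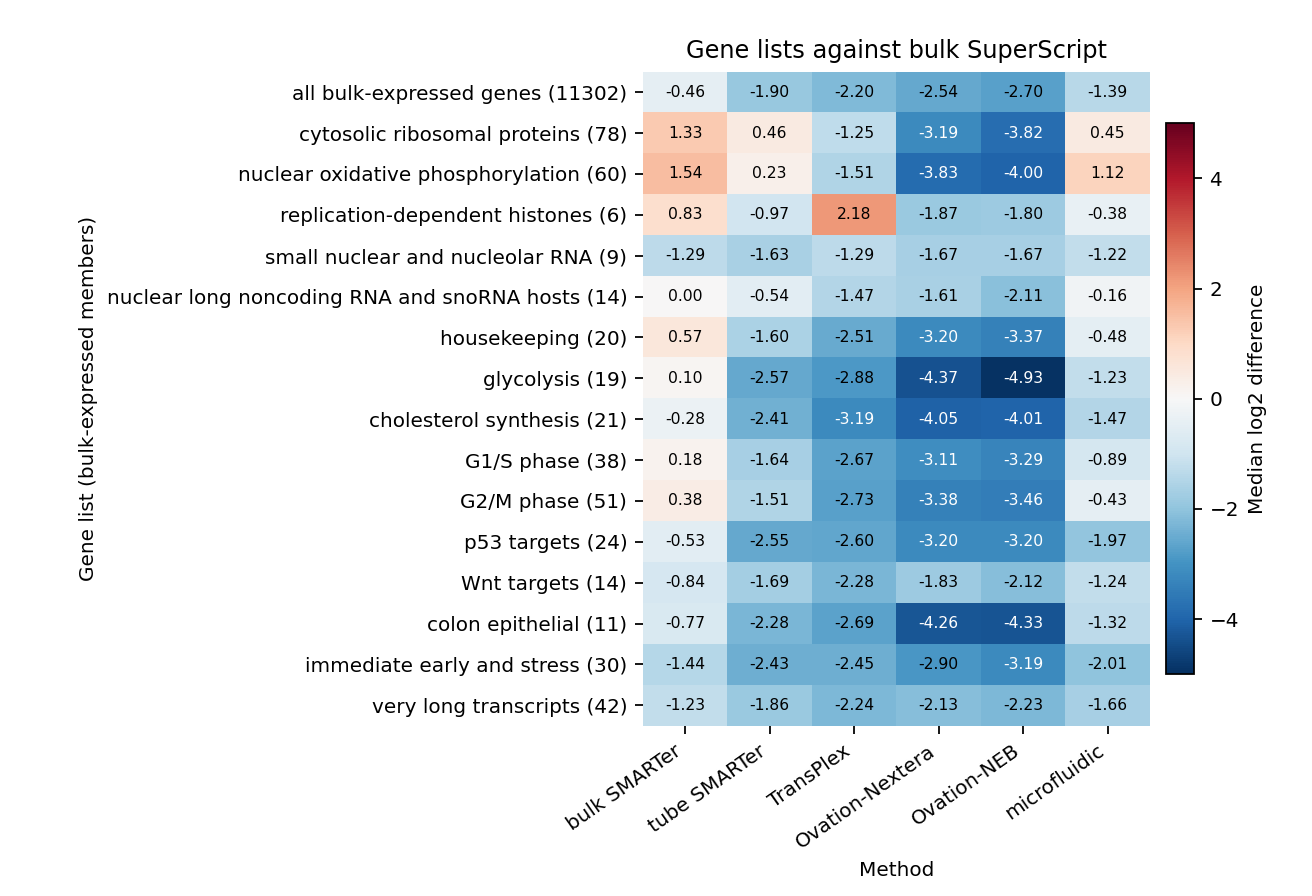
Median log2 difference from bulk SuperScript for the bulk-expressed members of each gene list (rows, number of members in brackets) in bulk SMARTer and the 5 single-cell methods (columns). Colour and printed value give the median, from the mean over libraries of log2 of FPKM + 1.

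Genes of the p53 response lay low among random lists of their bulk level, with medians of -2.55 in tube SMARTer (percentile 1.83), -2.60 in TransPlex (8.30), -3.20 in Ovation-Nextera (1.80), -3.20 in Ovation-NEB (5.16) and -1.97 in the microfluidic cells (0.72). With log2 of the mean FPKM the TransPlex percentile was 59.1 and the other methods ran from 0.35 to 6.73, and in TransPlex the cholesterol, glycolysis, G2/M, colon epithelial and G1/S medians were lower than that of p53 targets. The list of immediate early and stress genes, called immediate early below, was low in the microfluidic cells (-2.01, percentile 0.36). Its member FOS was not, with a mean of 107 FPKM there and 104 in bulk SuperScript. The list lay at -2.43 (17.5) in tube SMARTer, but at percentile 89.4 in TransPlex, 81.6 in Ovation-Nextera and 77.4 in Ovation-NEB. Glycolysis genes had -2.57 in tube SMARTer (percentile 9.39), -4.37 in Ovation-Nextera (10.7) and -4.93 in Ovation-NEB (7.13), against -1.23 (23.2) in the microfluidic cells and -2.88 (81.3) in TransPlex. G2/M genes were retained in the microfluidic cells (-0.43, percentile 100) and in tube SMARTer (-1.51, percentile 99.7). Very long transcripts were at percentile 100 in Ovation-Nextera (-2.13) and Ovation-NEB (-2.23), 97.1 in tube SMARTer (-1.86), 95.8 in TransPlex (-2.24) and 39.4 in the microfluidic cells (-1.66), and with log2 of the mean FPKM at 73.2 in tube SMARTer and 0.18 in the microfluidic cells. At percentile 100 in TransPlex (-1.47) were hosts of small nucleolar RNAs and long noncoding RNAs, which lay at 98.4 or above in the other 4 methods. Wnt targets had -1.83 in Ovation-Nextera (percentile 98.1), cholesterol genes -3.19 in TransPlex (25.2), housekeeping genes -1.60 in tube SMARTer (64.7), G1/S genes -1.64 there (98.7), colon epithelial genes -2.28 (18.6), small nuclear RNAs -1.63 (75.5) and fibroblast genes -1.75 (30.3). Log2 of FPKM + 1 cannot fall below 0, so such medians depend on bulk level, which the matched lists hold equal.

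Detection was lower in the class of highest GC content than in that of lowest in every method but TransPlex, where it was higher. Between the classes of lowest and highest GC, detection went from 94.6% to 42.4% of genes in bulk SMARTer, 65.2% to 32.2% in microfluidic cells, 49.2% to 24.5% in tube SMARTer, 26.2% to 13.3% in Ovation-Nextera and 19.9% to 9.86% in Ovation-NEB. TransPlex rose from 38.2% to 47.9% in the class below the highest, and had 43.9% in the highest. The classes differed in bulk level (median 13.6 and 3.66 FPKM), which alone lowers detection of the GC-rich class. By length, the shortest and longest classes had 60.9% and 48.2% in microfluidic cells, 48.2% and 33.7% in tube SMARTer and 52.7% and 38.6% in TransPlex, at bulk medians of 12.2 and 8.30 FPKM.

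**Figure D3:**
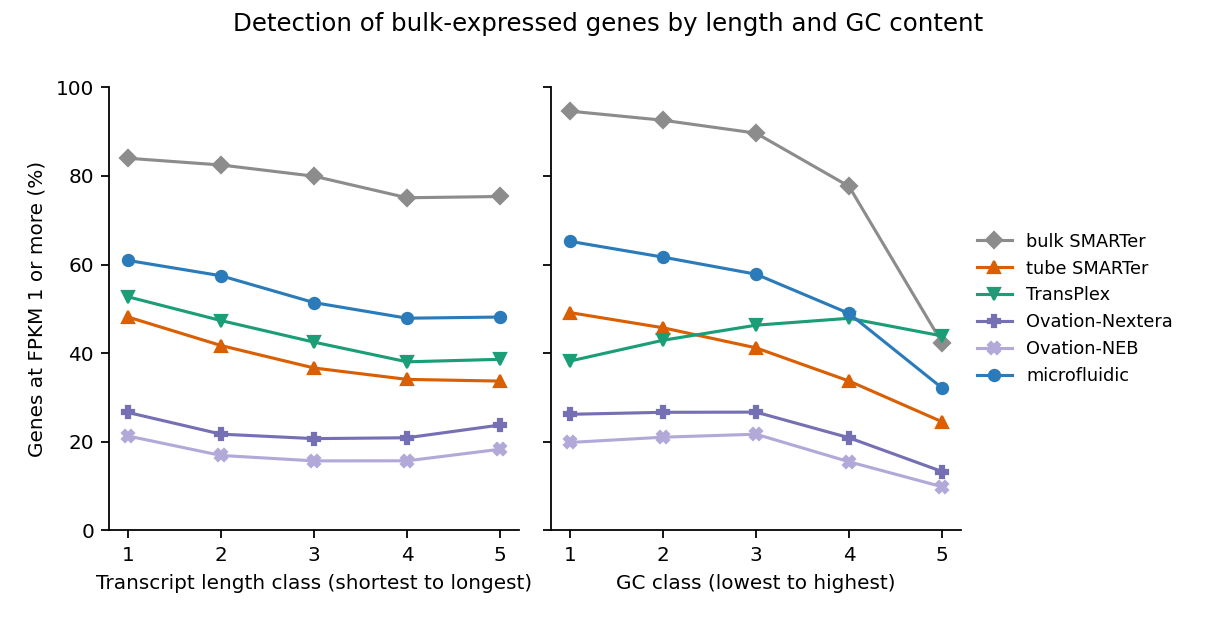
Mean percent of bulk-expressed genes detected per library (y, percent) in 5 classes of transcript length (left) and GC content (right), for genes of 300 nt or more. Lines mark the groups.

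Glycolysis and mitosis genes had lower mean levels in tube SMARTer cells (n = 3) than in microfluidic cells (n = 93), although both use SMARTer chemistry. Among genes at FPKM 10 or more the median difference was -0.85 log2 (tube minus microfluidic). Glycolysis genes lay at -2.37 with 15 of 16 lower (percentile 0 among random lists), and 9 lay below the 5th percentile of the microfluidic cells in all 3 tube cells. GAPDH, at position 6643585 to 6647537 of chromosome 12, had 159 and 1477 FPKM (-3.25), the aldolase gene ALDOA 33.5 and 409 (-3.41), GPI 12.1 and 156 (-3.43) and, with overlap, ENO2 0.0884 and 22.4 (-3.70). G2/M genes lay at -1.91 with 40 of 48 lower (percentile 0) but 0 of them below the 5th percentile of the microfluidic cells in all tube cells, cyclin B1, CCNB1, at 20.8 and 275 FPKM (-4.70), CCNB2 at 14.9 and 159 (-4.12), the kinesin KIF23 at 1.85 and 68.7 (-4.14) and PTTG1 at 32.5 and 342 (-3.75). These genes varied together across microfluidic cells (mean rho 0.454), which the random lists leave out. The cell cycle phase of only 3 tube cells could thus shift the whole list, which was not tested. Ribosomal protein genes lay at -0.23 with 33 higher and 45 lower (percentile 91.9), and on a TPM scale over genes of 300 nt or more at 0.38, with RPL12 at 452 and 77.4 FPKM (2.63) and RPS27 at 762 and 155 (2.33). Respiratory genes had 45 of 56 lower (-0.90, percentile 6.48). Among the other lists, housekeeping lay at -1.35 (percentile 2.65), Wnt targets at -1.73 (5.28), with the secreted inhibitor DKK1 at 2.50 and 58.2 FPKM, hosts of small nucleolar RNAs at 0.26 (96.9), with SNHG8 at 962 and 143 FPKM, and G1/S genes at -0.68 (65.4).

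Single genes outside those lists differed more widely between tube SMARTer and the microfluidic system. Below the 5th percentile of the microfluidic cells lay the calcium-binding S100A4 (11.2 against 515 FPKM, -5.72), the long noncoding UCA1 (2.91 and 202, -5.71), CHP (1.89 and 144.6, -5.99), PAIP2 (5.23 and 173, -5.43) and ZFAND6 (0.428 and 78.2, -5.33). RN45S and GPN1 were listed at 0 in tube SMARTer and at 243 and 63.5 FPKM. FOS (2.13 and 107, -5.15), EGR1 (2.40 and 75.6, -4.51), the cyclin CCNG1 (2.68 and 94.1, -4.82) and the squalene synthase FDFT1 (27.1 and 138, -3.05) had lower means but overlapped with the microfluidic cells, while the adhesion gene EPCAM was higher (305 and 92.9, 1.90). The highest differences fell on small RNAs such as MIR3064 and SNORD87 and, at 300 nt or more, on the nuclear copies of mitochondrial rRNA MTRNR2L6 and MTRNR2L10, which are near-identical and uncertain, and on RPL36A (77.2 and 5.65, 4.57). Across genes the group means correlated with r = 0.802. Kit format and depth differed together between these groups, and the reference used for counting may have differed too, so no difference here can be given to the format alone.

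Histone and structured noncoding RNAs set TransPlex (n = 3) apart from tube SMARTer (n = 3). Of 44 histone genes at FPKM 10 or more, 43 were higher in TransPlex (median 3.27 log2 against -1.72 for all genes at that level, percentile 100), and 20 did not overlap between the groups, as did 3.68% of all such genes in that direction. HIST1H2AG had 727 and 0.104 FPKM (6.84), HIST1H2AC 425 and 0.123 (6.55) and HIST1H4E 1301.6 and 29.7 (4.74). A mean FPKM of 10 in 1 group was enough to enter, and only 5 histone genes reached it in tube SMARTer or microfluidic cells. Most of the 44 thus entered through TransPlex alone. The count of 43, the 20 without overlap and the percentile were therefore largely set by the filter. Among all 63 measured histone genes, TransPlex had 52 at a mean FPKM of 1 or more, while tube SMARTer had 10. RMRP, the RNA of RNase MRP at position 35657748 to 35658015 of chromosome 9, had 154909 FPKM in TransPlex (59598 to 235784) and 0.570 in tube SMARTer, and the RNase P RNA RPPH1 had 1705 and 0, the small nucleolar SNORA23 3009 and 0, RNU12 92.2 and 0, and RNU4ATAC 6041 and 384. Small nuclear and nucleolar RNAs as a group had 12 of 14 higher (3.18, percentile 100), but members near 0 in tube SMARTer likewise entered through TransPlex alone.

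Genes of many functions were lower in TransPlex than in tube SMARTer, where the median was -1.72 over the 3291 genes at FPKM 10 or more in either group and 0 over bulk-expressed genes. COX7B had 14.2 and 615 FPKM (-6.31), the ribosomal MRPL47 0.115 and 103 (-6.53), the neurotrophic factor MANF 0.0826 and 99.5 (-6.37), PGRMC1 1.55 and 166 (-6.25), MGST1 14.9 and 500.4 (-6.06), the splicing regulator ESRP1 0.953 and 122 (-6.05) and TMSB4X 5.33 and 271 (-6.05). Ribosomal genes had 67 of 78 lower (-1.47, percentile 89.3), RPL7 at 29.3 and 641 FPKM (-4.37), but their median was -0.03 on the TPM scale over genes of 300 nt or more and 0.25 after centring on all genes. The clamp PCNA had 2.51 and 239 FPKM (-4.83) and the clamp loader RFC4 1.59 and 112 (-5.82), within G1/S genes at -2.00 (percentile 17.5). B2M had 13.9 and 626 (-5.72), the adhesion gene EPCAM 17.4 and 305 (-4.05) and the nuclear noncoding MALAT1 95.5 and 1689 (-4.66). Higher in TransPlex were KRT19 (51.3 and 6.76, 2.74), CCND1 (37.4 and 3.57, 3.40), FLNA (13.5 and 0.207, 3.17) and the anthrax toxin receptor ANTXR2 (236 and 0.0467, 7.78). Glycolysis lay at -0.25 (percentile 99.3), its sign changing with the scale, respiratory genes at -1.77 (46.6) and colon epithelial genes at -0.16 (97.5). On the TPM scale over genes of 300 nt or more the median of all genes was -0.78, and the group means correlated with r = 0.661 across genes.

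Respiratory and ribosomal messages were lower in Ovation-Nextera (n = 4) than in tube SMARTer (n = 3). Respiratory genes lay at -4.23 log2 with 47 of 53 lower (median -2.06 over the 3591 genes at FPKM 10 or more in either group and -0.28 over bulk-expressed genes, percentile 0), and 32 were lower without overlap, as were 34.1% of the 3591 genes. ATP5E had 2.42 and 759 FPKM (-8.45), COX7C 3.72 and 1166 (-8.34) and NDUFB4 0.134 and 283 (-7.84), and COX7A2 was listed at 0 and 332. Ribosomal genes lay at -3.27 with 76 of 78 lower (percentile 0.01) and 44 not overlapping, RPS29 at 23.5 and 1286 FPKM (-7.66) and RPL17 at 0.233 and 214 (-7.23). On the TPM scale respiratory genes lay at -3.83, and ribosomal genes at -2.24 stood little below all genes (-1.90) and above colon epithelial genes (-2.49). HIST1H4C had 0.162 and 2629 FPKM (-10.64), the antigen-presentation gene B2M, at position 45003685 to 45010357 of chromosome 15, 0.0227 and 626 (-9.25), the peroxiredoxin PRDX1 1.69 and 812 (-8.15), the proteasome gene PSMB1 0.0373 and 289.7 (-8.12), MGST1 1.08 and 500.4 (-8.31), LSM3 0.631 and 411 (-7.89) and PCNA 0.986 and 239 (-5.81).

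Single genes went the other way in Ovation-Nextera, often against the direction of their lists. The mitotic kinase gene PLK1 had 216 and 4.44 FPKM (5.21), the checkpoint kinase gene CHEK2 75.7 and 0.0136 (5.58), cyclin D1, CCND1, 155 and 3.57 (5.07), the trafficking gene ARF3 379 and 2.13 (5.80), MDN1 20.8 and 1.55 (3.33), AHNAK 14.6 and 0.690 (3.03) and NEAT1 86.9 and 13.3 (3.11). RPPH1 and AP1S1 were listed at 0 in tube SMARTer and at 1159 and 246 FPKM in Ovation-Nextera, and RMRP had 0.570 and 849. Small nuclear RNAs as a group lay at 2.91 with 5 higher and 4 lower (percentile 99.99), and very long transcripts at -0.33 (93.7), 9 of 14 lower, with a sign that changed with the scale. G2/M genes lay at -2.16 with 28 of 33 lower (percentile 32.4), G1/S genes at -2.02 with 22 of 29 lower (47.1), glycolysis at -2.11 (43.2), cholesterol genes at -1.05 (86.9) and immediate early genes at -0.58 (93.6). Group means correlated with r = 0.518 across genes.

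Library kits after Ovation amplification were compared without pairing, so spread between cells can hide kit effects. Ovation-NEB (n = 3) and Ovation-Nextera (n = 4) had group means that correlated with r = 0.943 across genes, with a median difference of -0.32 over the 1680 genes at FPKM 10 or more in either group (-0.73 on the TPM scale over genes of 300 nt or more) and 0.00 over bulk-expressed genes. SRP14, of the signal recognition particle, had 9.89 FPKM with NEB and 55.5 with Nextera (-2.66), the glycosylation gene DDOST 2.66 and 13.0 (-1.93), the ribosomal RPL12 8.50 and 24.2 (-1.56) and the phosphorylase MTAP 4.38 and 13.6 (-1.51). The pre-mRNA splicing gene PRPF38B had 134.9 and 49.0 (1.45) and LOC441454 182 and 14.7 (3.25). Ribosomal genes lay at -0.69 with 47 of 63 lower (percentile 0.26) and G2/M genes at 0.36 with 11 of 15 higher (percentile 98.5), RACGAP1 at 376 and 197 FPKM (1.14). Cyclin D1, CCND1, kept 232.5 and 155 FPKM, EPCAM 21.8 and 21.8. Only 0.179% of the 1680 genes were higher and 0.833% lower without overlap. The chance value of 2.86% each way takes the 7 libraries as independent. The libraries fell into sets that crossed the kits, as given next, so this value cannot judge those shares. Differences within sets were not examined, so single genes of this comparison carry little weight.

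Individual Ovation libraries fell into 3 sets that crossed the 2 kits: Nextera 2, Nextera 4 and NEB 1, then Nextera 3 and NEB 3, then Nextera 1 and NEB 2. Within sets r was 0.949 to 0.961 between kits across bulk-expressed genes, against 0.995 for the pair of 1 kit, and between sets 0.391 to 0.591. Nextera 2 and Nextera 4 were that pair, and both were kept as libraries. Whether they were 1 library sequenced again could not be told.

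**Figure D4:**
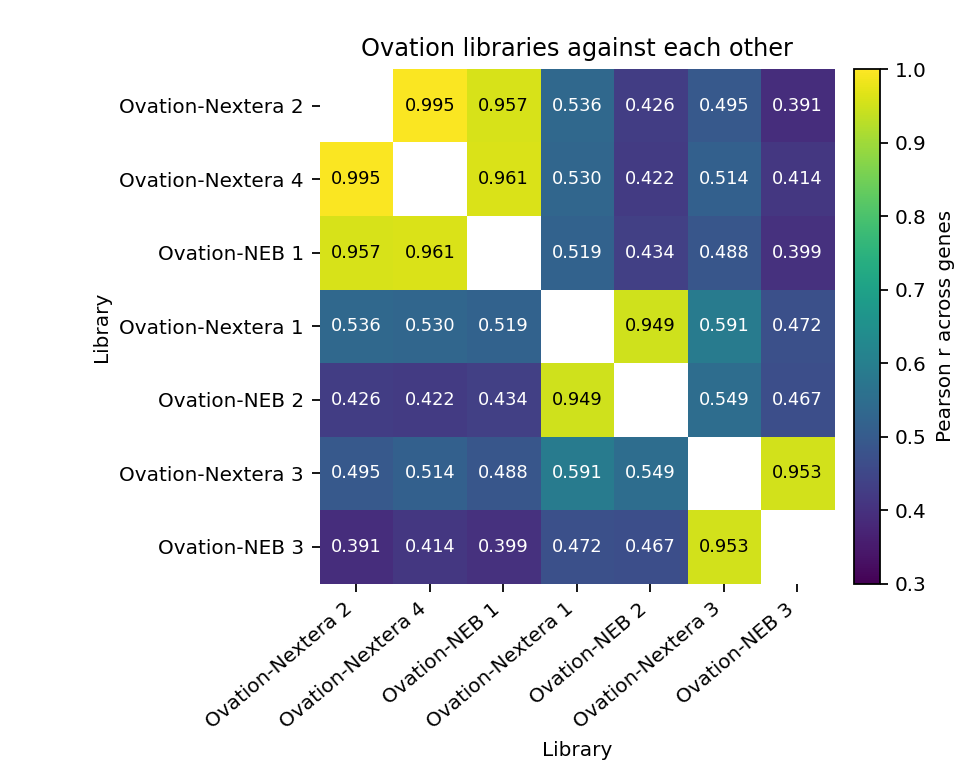
Pearson r between the 7 Ovation libraries across bulk-expressed genes, as log2 of FPKM + 1. Rows and columns are libraries, named by library kit and replicate.

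Genes that varied most from cell to cell in the microfluidic system included SAT1, and their ranking depended on scale and libraries. Over 93 cells SAT1, the polyamine acetyltransferase, had a mean of 862 FPKM and a coefficient of variation (CV) of 2.07, the only gene of 300 nt or more among the 12 furthest above the trend of variability with level. At 300 nt or more, and in most cells, it was followed by HIST1H4C (3646 FPKM, CV 0.857), the autophagy gene MAP1LC3B (34.3, CV 2.60), the metallothionein MT1X (145, CV 1.67), the ferritin heavy chain FTH1 (244, CV 1.19), the importin KPNA2 (548, CV 0.883), the ubiquitin conjugase UBE2C (215, CV 1.01), UCA1 (202, CV 1.02), DKK1 (58.2, CV 1.41), the phosphatase DUSP6 (281, CV 0.854) and the mitotic kinase CDK1 (233, CV 0.891). A single cell carried the value of MAP1LC3B (854 FPKM, CV 0.978 without it), and MT1X and IDI1 fell to CV 1.14 and 0.898 without their highest cell. Furthest below the trend lay RPSAP9 (15.0 FPKM, CV 0.392), EEF2 (19.9, CV 0.380), NBPF10 (11.3, CV 0.481), HDLBP (22.5, CV 0.387), RPL10 (56.5, CV 0.302) and HUWE1 (17.5, CV 0.458), with RPS23 (96.8, CV 0.274) and RPL32 (96.7, CV 0.279) also among the 12 furthest. The other genes above it by rule were small RNAs, among them VTRNA1-3 and SNORA27, detected in 17 and 15 cells. On the TPM scale 1 of the 12 genes furthest above and 4 of the 12 furthest below were shared with this ranking, and without the first library pool 5 and 10.

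By group, 35 of 48 G2/M genes lay above the trend (percentile 99.95 of matched lists) and 12 of 14 cholesterol genes (99.97), IDI1 (CV 1.24) and NSDHL (CV 1.48) among them. Of 77 ribosomal genes 69 lay below (percentile 0), as did 41 of 56 respiratory genes (0) and 9 of 10 very long transcripts (0.01). Glycolysis had 11 of 15 above (96.2), G1/S 19 of 29 (93.5), histones 3 of 3 (99.3), immediate early genes 7 of 14 (51.9) and Wnt targets 4 of 7 (48.6). The median squared CV was 0.677 over 3699 genes, and at 300 nt or more it was 0.765 at mean FPKM 10 to 100, 0.200 at 100 to 1000 and 0.0902 above that. ERCC spike-ins had 4.08, 2.70 and 1.78 in the same classes, and 1.87, 0.294 and 0.105 without the cells that had more than 50% of summed FPKM in spike-ins (genes 0.715, 0.175 and 0.0732). Genes below 300 nt had 8.39, 4.55 and 2.67 over all cells.

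Mitotic genes varied together across the 93 microfluidic cells. The mean Spearman rho between G2/M genes was 0.454 against a median of 0.0873 for random lists, and between G1/S genes 0.295 against 0.0751, both at percentile 100 of 1000 lists. CKS2 (0.586), the centromere gene CENPF (0.585), topoisomerase TOP2A (0.562), CENPE (0.551), KIF23 (0.544) and cyclin B1, CCNB1, (0.541) had high mean rho with the other G2/M genes. Between G1/S and G2/M genes the mean rho was 0.0215. After regression on the number of detected genes the values were 0.409 for G2/M, 0.240 for G1/S and -0.0627 between them. Ribosomal genes (0.328 against 0.137), glycolysis (0.286 against 0.110), cholesterol synthesis (0.218 against 0.0731), respiratory genes (0.199 against 0.117), histones (0.171 against 0.0457) and p53 targets (0.105 against 0.0495) were at percentile 100 as well. Housekeeping (0.138, percentile 88.1), colon epithelial (0.0996, percentile 91.7), immediate early (0.0724, percentile 70.4) and Wnt genes (0.0615, percentile 39.1) were not. Within each of the 4 library pools G2/M and G1/S genes stayed at percentile 100.

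Quantitative PCR of 40 assays ranked the genes much as the microfluidic RNA-seq did. Across assays, which are not independent replicates, Spearman rho was taken between the medians over cells of PCR level and of log2 of FPKM + 1. It was 0.884 on chip 1 (88 cells), 0.892 on chip 2 (90 cells) and 0.874 in tube cells (257 cells). Within the 23 assays seen in over 10% of cells by both, rho between means over cells, in place of medians, was 0.626, 0.663 and 0.374. The abundant GAPDH and ACTB had product in 100% of cells, and the colon differentiation genes MUC2, OLFM4, CFTR and SLC26A3 in 0% to 3.41%. FSCN1, an actin bundler, had product in 100%, 100% and 98.1% of cells against detection in 11.8% by RNA-seq, BMI1 in 98.9%, 100% and 99.6% against 10.8%, TERT in 86.4%, 84.4% and 30.7% against 1.08%, BMPR1A in 100% against 37.6% and the Wnt effector TCF7L1 in 100%, 98.9% and 98.1% against 52.7%. All of these genes were also lower in bulk SMARTer than in bulk SuperScript. FSCN1 had 0.0932 and 6.11 FPKM, BMI1 2.75 and 8.39, TERT 0.0108 and 0.192, BMPR1A 2.78 and 12.4 and TCF7L1 0.677 and 2.60. Their low detection thus cannot be given to the use of single cells alone. Mitotic genes had product in fewer tube cells, and in more cells of both chips, than RNA-seq detected: ANLN in 100%, 98.9% and 82.1% against 93.5%, BIRC5 in 98.9%, 98.9% and 80.9% against 95.7% and TOP2A in 98.9%, 98.9% and 82.9% against 94.6%. Across cells ANLN and TOP2A had rho 0.859, 0.896 and 0.883 by PCR and 0.661 by RNA-seq, while GAPDH and ACTB had 0.642, 0.560 and 0.416 against 0.0450. PCR levels were not scaled per cell, while FPKM is scaled to library size, so these rho values are unlike measures. The PCR cells match no sequenced library, and their table names no cell line.

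**Figure D5:**
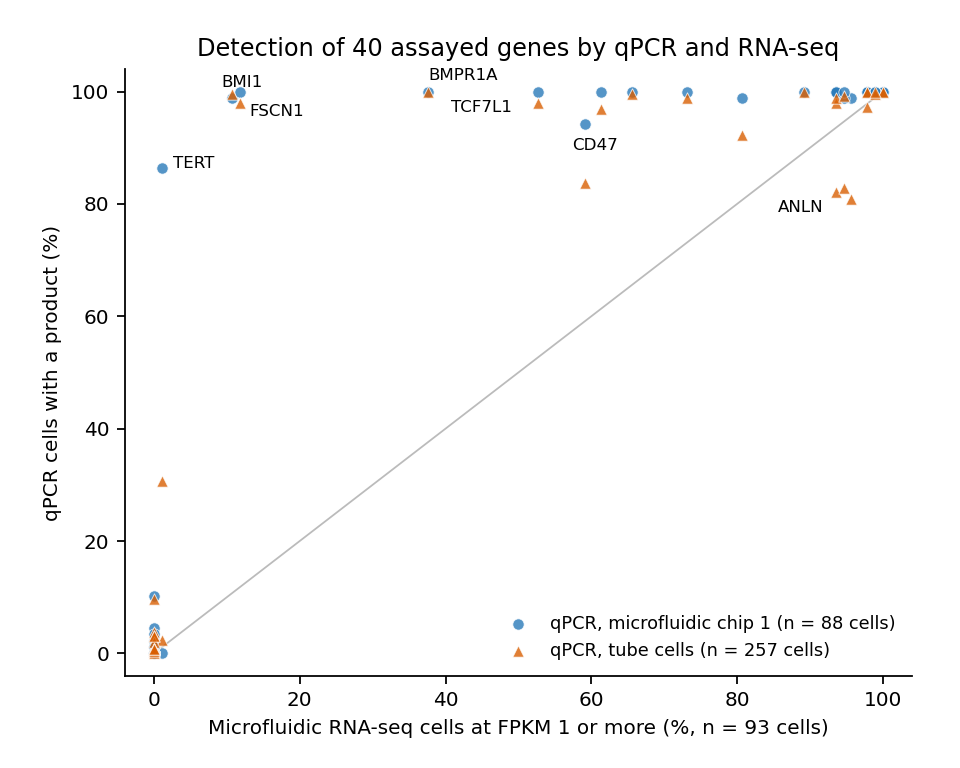
Percent of cells with a PCR product for each of 40 assays (y) against percent of 93 microfluidic cells with the gene at FPKM 1 or more (x). Circles are microfluidic chip 1 (88 cells), triangles tube cells (257 cells), and the line marks equal values.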

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

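The tests of different cells in the same state, of RN45S recovery, of mitochondrial copies and both tests of a fixed FPKM limit were chosen after the result was seen.

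Ovation-Nextera 3 correlated with bulk SuperScript at 0.504, which stood apart from the other 3 libraries of its group (0.377 to 0.398). Dixon's test gave a ratio of 0.835 against a critical value of 0.829, and chance passes it in about 1 in 20 groups, while the counts of detected genes in this group did not pass. This library had the greatest implied depth of its group (12490036 fragments), but Ovation-NEB 3, of the same set, also had the highest value of its kit (0.456 against 0.326 and 0.366) at 4126905 fragments, fewer than the 4379600 of NEB 1. Nextera 2 and 4 correlated at 0.995, so the 4 values behind this test are not independent. Without it the mean of the Ovation-Nextera cells correlated with bulk at 0.424 in place of 0.502.

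Of 3 microfluidic libraries with a control in the file name, 2 held far more genes than the control without template. Microfluidic 70, named as having no template, had 242 detected genes, 99.8% of its summed FPKM in spike-ins, and r = 0.214 with bulk. Microfluidic 42, named as an RNA control, had 6021 genes, 29.5% in spike-ins and r = 0.679, and microfluidic 92, named as a cell control, had 7382 genes, 10.7% in spike-ins and r = 0.747. Their correlations with the mean of the 93 cells were 0.249, 0.783 and 0.886. Titles place all 3 among the single cells, and whether 42 and 92 hold 1 cell could not be settled from the tables.

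The 7 Ovation libraries correlated in 3 sets across the 2 library kits. Abundant genes alone did not carry the sets, since genes at bulk FPKM 1 to 10 correlated within sets at 0.920 or more and between sets at 0.485 or less. Nextera 2 and 4 differed by more than simulated draws from 1 pool, with a chi-square per degree of freedom of 2.28 over 2010 genes against 0.963. The bulk pairs had 2.35 and 4.45. These counts were estimated from intervals, an error the simulation leaves out, so 1 library sequenced again could not be excluded. Different cells in the same state would also give high values, but the lowest r within a set, 0.949, lay above the highest between any 2 microfluidic cells, 0.792. Amplified cDNA shared within a set stays open as a candidate explanation, by which the 7 libraries would stand for 3 cells: deviations from the mean of the 7 libraries correlated within sets at 0.809 or more, but this restates the sets, and centring alone gives values near the -0.616 to -0.349 seen between them.

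The rRNA precursor RN45S was listed at 0 in the 13 tube-method libraries and was present elsewhere. A candidate explanation is that these libraries were counted on a reference without the unplaced and alternative contigs: of 23 genes found on such contigs alone, 0 were above 0 in a tube-method library, although 7 had bulk FPKM 1 or more. All 1292 such rows were at 0 there, while bulk libraries had 810 to 931 above 0 and microfluidic ones 83 to 438. Failure to recover RN45S from a single cell cannot be general, as 100% of microfluidic cells had it. Missing sequence may also have sent mitochondrial rRNA reads to nuclear copies, as 9 of 9 MTRNR2L genes had the higher mean pooled over tube libraries (MTRNR2L8 5556 against 34.0 FPKM), although for MTRNR2L3 this came from tube SMARTer alone (87.7), the other tube groups being at 3.00 to 4.08 against 4.69.

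Microfluidic cells had the most detected genes of the single-cell methods at the lowest depth. A fixed FPKM limit may favour shallow libraries, where a single fragment passes it. At 100000 implied fragments TransPlex had 7123 genes with a fragment against 5981 in microfluidic cells, so that the order of these 2 turned. It did not for tube SMARTer and Ovation, whose highest mean was 4864. Implied fragments are estimates, and the 8 microfluidic cells with the fewest fragments of genes, spike-ins not counted, were left out of this test.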

How the results depend on the processing

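Tests marked here as added, namely TPM over genes of 300 nt or more, centring, crossed blocks, equal implied fragments, genes of 300 nt or more, removal of libraries rich in spike-ins, averaging of Ovation-Nextera 2 and 4, and log2 of the mean FPKM, were chosen after results were seen. Of 1007 alternative values, 654 stayed with the main value and 353 moved: a count of different genes or of called lists stayed if within 1.5 times the main count, another value if within 1 SD. The SD was that between libraries, between pairs of libraries for correlations within a method (for the bulk pairs, between their 2 values), and for microfluidic spread and covariation that between library pools, while for PCR it was replaced by 0.5 of the range when each assay was left out. Limits common to the results are the lack of named separate cultures, the 2 technical replicates of each bulk kit, the estimate of depth from intervals, the matching of length and GC by symbol, and tube-method libraries with all rows of other contigs at 0; the cause of a move was not tested unless its construction shows it. Values are given with the main value in brackets.

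Bulk counts were 1150 higher (3759) and 8401 lower (5286) on the TPM scale, 1999 and 8202 on it over genes of 300 nt or more, 1733 and 3689 at 2-fold or more, and 2823 and 1592 at FPKM 10 or more. The remaining bulk settings gave 3711 to 3776 higher and 5256 to 7175 lower, except centring on the median, with 4573 and 4579. Leaving out a library gave 3250 to 3788 higher and 4405 to 5606 lower, taking the lone library to vary like the others. Taking the replicate number as a block gave 3805 and 5342, the crossed pairing 3821 and 5365, and the deviations of same-numbered replicates correlated at -0.17, so the numbers gave no sign of pairs. Of 16 lists, camera with estimated correlation called 0 (6), with 0 at unadjusted p below 0.05 and a lowest adjusted p of 0.421, and fry called 13, a test of direction alone. With 2 libraries per kit, camera with estimated correlation can hardly call a list.

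With detection at any value above 0, genes per library were bulk SuperScript 16165.5 (11286.5), bulk SMARTer 14661 (9189.5), tube SMARTer 8711 (4698), TransPlex 10217 (5393), Ovation-Nextera 7140.5 (2698), Ovation-NEB 5376 (2069) and microfluidic 7415 (6111), and the share of bulk-expressed genes in percent was tube SMARTer 64.3 (38.4), TransPlex 73.2 (43.5), Ovation-Nextera 56.5 (22.7), Ovation-NEB 43.4 (17.5) and microfluidic 61.7 (52.4). At FPKM 10 or more the counts were bulk SuperScript 5269.5, bulk SMARTer 4465.5, tube SMARTer 2420.3, TransPlex 1149.7, Ovation-Nextera 1145, Ovation-NEB 941 and microfluidic 3359, and the shares tube SMARTer 20.3, TransPlex 9.07, Ovation-Nextera 9.61, Ovation-NEB 8.00 and microfluidic 29.3. On the TPM scale the counts were bulk SuperScript 13005.5, bulk SMARTer 10284, TransPlex 7216, Ovation-Nextera 4277 and Ovation-NEB 3365, with shares of TransPlex 56.5, Ovation-Nextera 35.5 and Ovation-NEB 28.1. At equal implied fragments the counts were bulk SuperScript 9846.5, bulk SMARTer 8018.5, TransPlex 7123, Ovation-Nextera 3413.5 and Ovation-NEB 2537, with shares of TransPlex 55.9, Ovation-Nextera 28.7 and Ovation-NEB 21.4. Construction explains the direction of the first 2 settings. Counts and shares with a replicate left out all stayed.

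Correlations moved with the choice of genes and measure. Spearman rho between libraries of a method was bulk SuperScript 0.982 (0.969), tube SMARTer 0.652 (0.581), TransPlex 0.525 (0.634), Ovation-Nextera 0.778 (0.533) and Ovation-NEB 0.617 (0.434), with bulk it was TransPlex 0.492 (0.550) for single libraries and 0.574 (0.626) for the TransPlex mean. Genes at bulk FPKM 10 or more gave bulk SuperScript 0.910 (0.969) and bulk SMARTer 0.974 (0.986) between libraries, microfluidic 0.581 (0.689) for single libraries and tube SMARTer 0.614 (0.698) and microfluidic 0.736 (0.849) for means of cells. Bulk SMARTer as the reference gave TransPlex 0.491 (0.550) and Ovation-Nextera 0.354 (0.418) for single libraries and TransPlex 0.559 (0.626), Ovation-Nextera 0.433 (0.502), Ovation-NEB 0.404 (0.470) and microfluidic 0.917 (0.849) for means. All genes above 0 gave 0.988 for the bulk SuperScript pair and 0.587 for the TransPlex mean, and genes of 300 nt or more gave the bulk SuperScript pair 0.995. Between libraries a pseudocount of 0.1 gave bulk SuperScript 0.948, TransPlex 0.558 and Ovation-NEB 0.520, 1 of 10 gave TransPlex 0.713, and the TPM scale gave TransPlex 0.584 and Ovation-NEB 0.521.

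Leaving out a replicate gave between libraries 0.554 to 0.636 in tube SMARTer, 0.572 to 0.648 in TransPlex and 0.399 to 0.467 in Ovation-NEB, each with its moved value without replicate 2. Means of cells ran 0.609 to 0.691 in tube SMARTer (lowest without replicate 1), 0.591 to 0.616 in TransPlex (lowest without replicate 2), 0.424 to 0.505 in Ovation-Nextera and 0.389 to 0.474 in Ovation-NEB (both lowest without replicate 3).

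Differences of lists from bulk SuperScript depend on floor and scale, as the main values in the report and these show. Bulk SMARTer as the reference gave ribosomal genes tube SMARTer -0.93, TransPlex -2.35 and microfluidic -0.88, then respiratory genes tube SMARTer -1.26, TransPlex -2.96, Ovation-Nextera -4.66, Ovation-NEB -5.13 and microfluidic -0.37, then histones tube SMARTer -2.11, Ovation-Nextera -3.89 and Ovation-NEB -3.71, which reversed the sign of ribosomal and respiratory genes in tube SMARTer and microfluidic cells. A pseudocount of 0.1 gave respiratory genes Ovation-Nextera -5.28 and Ovation-NEB -6.10, then histones tube SMARTer -3.09, Ovation-Nextera -4.53, Ovation-NEB -4.16 and microfluidic -1.88, and 1 of 10 gave respiratory genes Ovation-Nextera -1.63 and Ovation-NEB -1.75, then histones tube SMARTer -0.14, Ovation-Nextera -0.37 and Ovation-NEB -0.36. The TPM scale gave respiratory genes Ovation-NEB -4.73, then histones tube SMARTer -2.03, Ovation-Nextera -3.07 and Ovation-NEB -2.65. Log2 of the mean FPKM gave respiratory genes Ovation-Nextera -3.21. Of the 70 values of the 14 lists not named here, 29 stayed and 41 were lower on the TPM scale, 20 stayed and 50 were lower at pseudocount 0.1, 12 stayed and 58 were higher at pseudocount 10 (1 changed sign), 34 stayed, 31 were higher and 5 lower with bulk SMARTer as the reference (2 changed sign), and 45 stayed, 18 were higher and 7 lower as log2 of the mean (5 changed sign). Of 56 values each, 48, 48 and 47 stayed without replicate 1, 2 or 3, with 1 change of sign without replicate 2.

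In microfluidic cells the median squared coefficient of variation was 0.200 at mean FPKM 100 or more and 1.26 on the TPM scale (0.677). Mean rho was 0.436 within the first library pool and 0.174 within the fourth for G1/S genes (0.295), and 0.349 within the fourth for G2/M genes (0.454). With undetected assays left out, PCR against RNA-seq had rho 0.641 on chip 1 (0.884), 0.665 on chip 2 (0.892) and 0.638 in tube cells (0.874), and means over cells gave tube cells 0.847. Putting back the 3 libraries named as controls moved none of the values tested with it.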

Other observations

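All values in this part were looked up after the results were seen, apart from the gene lists of cell types and the spike-in shares.

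Genes of other tissues appeared at high level in single methods. Insulin, INS, at position 2181009 to 2182439 of chromosome 11, had 106.9 to 529.6 FPKM in the 3 TransPlex libraries and was listed at 0 in the libraries of the other groups. In the 3 tube SMARTer libraries the synaptic gene SNAP25 had a mean of 114 FPKM (13.0 to 205), the neuronal GPM6A 36.4 (10.1 to 59.5) and STMN2 15.9 (10.3 to 21.7). SNAP25 was listed at 0 in TransPlex, Ovation and microfluidic libraries and at 0.737 FPKM in bulk SuperScript, GPM6A was at 4.40 FPKM in bulk SuperScript and detected in 11.8% of microfluidic cells, and STMN2 was listed at 0 in both bulk kits. CD68, a lysosomal gene of macrophages and other cells, had a mean of 126 FPKM in Ovation-Nextera and 412 in Ovation-NEB, 5.13 in bulk SMARTer, and less than 1 in tube SMARTer and TransPlex.

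Of 20 leukocyte genes, the microfluidic cells had 1 at a mean FPKM of 1 or more, HLA-DRA at 3.11, and bulk SuperScript had 3, the highest HLA-DRA at 2.13. Of 12 endothelial genes the highest in any group was ESAM in TransPlex at 1.55 FPKM. Fetal haemoglobin HBG2 was the only erythroid gene at 1 or more, with 12.6 FPKM in tube SMARTer, 7.24 in bulk SMARTer, 4.11 in bulk SuperScript and 3.42 in the microfluidic cells. Of 20 fibroblast genes 7 reached 1 in bulk SuperScript and 3 in the microfluidic cells, S100A4 the highest at 193 and 515 FPKM. Wnt targets had CD44 as their highest member in bulk SuperScript (205) and in the microfluidic cells (174), and CCND1 in both Ovation groups (155 and 232.5).

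Stress genes differed in spread across microfluidic cells at similar levels: DDIT3 had a mean of 14.4 FPKM with a coefficient of variation of 1.87 and was detected in 49.5% of cells, while the p53 target MDM2 had 18.9 and 1.18 and was detected in 90.3%. The nuclear MALAT1 (662 FPKM, 0.515) and GAS5 (222, 0.514) were in 100% and 97.8% of cells, and cyclin E2, CCNE2, had 14.1 FPKM with 1.63.

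Spike-ins made up a mean of 24.7% of summed FPKM in the microfluidic cells (4.04% to 99.0%), and 3 cells had more than 50%. The cell with the fewest genes, 479, had the highest share. In PCR, chambers scored as holding no cell gave product in 0 to 7 of 40 assays, MYC among them, and controls without template in 0 or 1, which was ACTB. Repeat runs of the same cells differed with an SD of 0.299 Ct on chip 1 and 0.434 Ct on chip 2. Correlations of gene pairs across cells agreed between the 2 chips at r = 0.536 over 190 pairs, and between the chips and RNA-seq at 0.325 and 0.357. PCR levels were not scaled per cell, unlike FPKM.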
